A study of Rattus norvegicus with 12 samples.

How the data were processed

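RNA-seq was measured in skeletal muscle of rats aged 540 days, born to dams on a control diet or on a protein-restricted diet. The labels gave 12 libraries, 6 control and 6 maternal protein restriction, with a number in each title. The numbers fell into 2 sets, with 3, 8, 9 (control) and 12, 13, 15 (restriction) in set 1, and 23, 28, 29 (control) and 32, 33, 35 (restriction) in set 2. The series description names soleus and extensor digitorum longus as the muscles taken, and the labels used here do not tie a muscle to a library, so the sets are called set 1 and set 2. Nothing in the labels says that the libraries came from separate animals, so the p-values measure the spread between these libraries, which may be technical in part. A library of set 1 and one of set 2 may come from the same animal. The diet was given to the dams, and the labels used here name no dam or litter. Libraries of a group may thus come from littermates, which the p-values and SE do not allow for.

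Per the labels, RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit, which does not mark strand, so reads of a gene and of an antisense partner cannot be told apart. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2, featureCounts and DESeq2 with the build Rnor_6.0. Their versions, their order and the annotation release are not given in the sources used here. The deposited table holds raw counts per gene, which are whole numbers summing to between 22829692 and 38313704 per library. A second deposited table equals the counts divided by 1 constant per library and was not used. Of 24648 rows, 17922 carried a current rat gene symbol and 2141 more a synonym in a RefSeq gene table of another assembly (GRCr8), which was used for names alone, so no coordinates are given. There were 144 names on more than 1 row, and those rows were kept separate.

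From the counts, genes were filtered with filterByExpr over the 4 set-by-treatment groups of 3 libraries, which kept 14225 genes. Scaling was by TMM, and edgeR 4.0.16 in R 4.3.3 fitted 1 mean per group over all 12 libraries, with quasi-likelihood tests, Benjamini-Hochberg adjustment and a threshold of 0.05. The contrasts were restriction against control in set 1, in set 2 and averaged over both, the difference between the sets in that effect, and set 2 against set 1. Log2 fold changes are restriction minus control, or set 2 minus set 1, with SE. CPM values are scaled by TMM, and are means with SD of 3 libraries. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with an estimated correlation. Lists needed 5 tested members, and 26 were tested. A list of the 13 proteins encoded by mitochondrial DNA had no member among the row names and was not tested.

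The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named, per contrast, up to 8 called genes higher and 8 lower by size of change, with mean CPM of at least 1 and no overlap between groups, up to 4 called members per list, and 8 genes that the series description names (Sdha, Cs, Ldha, Igf1, Chad, Fmod, Hspb7 and Myog). Where fewer than 5 genes were called in a direction all were named, and where none was, the 5 with the smallest p were named as not passing. Loci named only by LOC or RGD with a number, and names on more than 1 row, did not count as genes with a symbol and were passed over in these choices. List members named in the treatment comparisons beyond that rule were chosen after their values were seen, as those with the smallest p over the list.

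Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors or library size alone as scaling, no filter on low counts, a filter of mean CPM of at least 1, only the libraries of 1 set, no set term, a replicate block on the title number, and leaving out each library. Leaving out the mitochondrial tRNA and rRNA rows was added after seeing the data. The fit was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, all changed together and with a mean CPM of at least 1. It recovered 43% and 85% of them in set 1 (13918 genes tested), 40% and 86% in set 2 (13925 genes) and 70% and 95% for the mean over both sets (13946 genes). No 2 libraries of a group agreed within sampling noise, with chi-square per degree of freedom from 24.5 to 146.6.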

Results

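Transcript counts were obtained from muscle of 540 day old rats whose dams had been fed a control or a protein-restricted diet. The 12 libraries comprised 3 control and 3 restriction libraries in each of 2 sets of title numbers. Total counts per library ran from 26506707 to 38313704 in set 1 controls, from 22829692 to 26037169 in set 1 restriction libraries, from 22869995 to 30146567 in set 2 controls and from 29288433 to 31342247 in set 2 restriction libraries. The first principal component held 47.9% of the variance and separated the sets. The second held 11.2% and set control 23 apart from the other libraries, at 88 against values from -23.7 to 19.6.

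**Figure D1:**
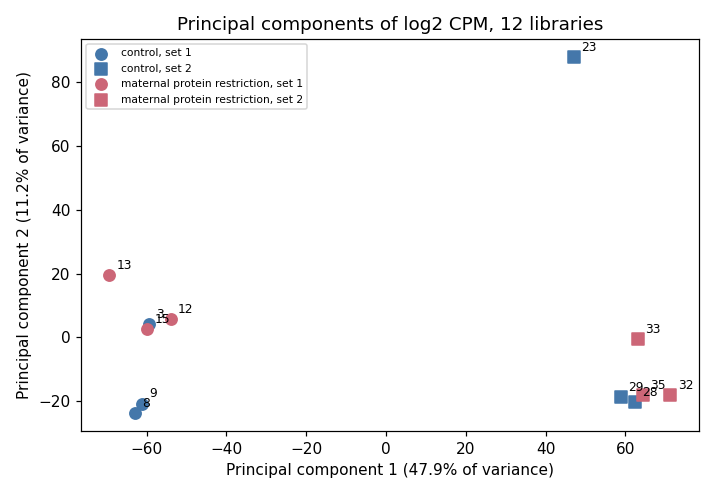
Principal components 1 and 2 of log2 CPM for the 12 libraries, numbered by title, with circles for set 1, squares for set 2, blue for control and red for maternal protein restriction. The sets lie on opposite sides of component 1 (47.9% of variance), and control 23 lies at 88 on component 2 (11.2% of variance).

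The first comparison set the 2 sets against each other over both diets. Set 1 carried the transcripts of the slow contractile apparatus and set 2 those of the fast one. Myh7, the slow myosin heavy chain, measured 35500 CPM in set 1 controls and 1750 CPM in set 2 controls, with a log2 fold change of -4.26 ± 0.29 (SE). Myh4, the fast type IIB heavy chain, rose from 140 to 15400 CPM in the controls, with a log2 fold change of 9.07 ± 0.96 over both diets. Of 14 tested fast-fibre genes all 14 rose and of 13 slow-fibre genes all 13 fell in set 2, each at an adjusted p below the threshold in edgeR's quasi-likelihood test. Camera with an estimated correlation called neither list (adjusted p = 0.12 and adjusted p = 0.21).

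Among fast-fibre genes, Atp2a1, the fast calcium pump, was higher by 4.01 ± 0.16 on the log2 scale (SE), Tnnc2 by 3.69 ± 0.17, Tnni2 by 3.79 ± 0.22 and Myoz1 by 4.33 ± 0.19. Besides Myh4, the genes with large increases were Mybpc2 (8.15 ± 0.94), Myh1 (7.83 ± 0.67), Actn3 (7.63 ± 0.93), Pvalb (7.50 ± 0.90) and Ush1c (7.45 ± 0.66). Control 3 held 396 CPM of Myh4 against 19.5 and 4.97 in the other set 1 controls. Without it the log2 fold changes were 10.83 for Myh4, 9.82 for Mybpc2, 8.58 for Myh1, 9.33 for Actn3 and 9.05 for Pvalb. Ush1c was at 9.31 without restriction 15, which left the restriction group of set 1 at 0 counts, so this value depends on the prior count. Foxl2 had 8 counts in control 3 and 0 in the other set 1 libraries, and 2.74 to 5.52 CPM in set 2. Myosin heavy chains are close paralogs, and reads they share are uncertain. Tmem132b had 0 counts in the 6 set 1 libraries and was at least 161-fold higher in set 2, against a floor of 3 counts over the group. On the slow side the log2 fold changes were -4.71 ± 0.23 for Myl3, -5.56 ± 0.27 for Tpm3, -4.90 ± 0.26 for Tnnt1 and -4.27 ± 0.24 for Tnni1. Zfp474 and Fam216b had 0 counts in set 2 and were at least 476-fold and 248-fold higher in set 1. Gnat3, Sim2, Gsdma, Mettl21c and Cacna1e were lower in set 2 by log2 values from -8.62 to -7.49. The value was -10.49 for Gnat3 without restriction 33, -10.05 for Sim2 without control 29 and -9.33 for Cacna1e without control 28, which held 5, 6 and 4 counts, the only ones of their diet group in set 2, so these values depend on the prior count. Gsdma was at -8.66 without restriction 35. Kif4a, with 2 counts in set 2 and 340 in set 1, was lower there too.

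In metabolism, 14 of 15 tested glycolysis genes rose in set 2, among them Pfkm (2.78 ± 0.13), Pkm (2.60 ± 0.13) and Ldha (2.94 ± 0.15), and none fell. In the fatty acid oxidation list 10 of 22 fell and 2 rose, with Lpl at -2.09 ± 0.24 and Fabp3 at -1.53 ± 0.23. The citric acid cycle list had 8 of 18 higher and 1 lower, with Idh3a at 1.60 ± 0.15 and Idh2 at -0.82 ± 0.13. Of 22 fibrillar matrix genes 18 fell, including Loxl1 (-2.51 ± 0.19), Bgn (-2.30 ± 0.24) and Fbn1 (-1.62 ± 0.20). Of 17 heat-shock genes 9 fell, with Cryab at -2.24 ± 0.18 and Hspb7 at -2.62 ± 0.24. In the list of genes known to respond to denervation 9 of 16 fell and 3 rose, with Chrnd, an acetylcholine receptor subunit, at -3.27 ± 0.14 and Sln, a calcium pump regulator, at -6.55 ± 0.28. With an estimated correlation camera called none of these 6 lists, with an adjusted p = 0.12 for glycolysis and denervation, 0.67 for fatty acid oxidation and the citric acid cycle, 0.42 for fibrillar matrix and 0.36 for heat-shock genes. Of the lists of other cells, 3 were called lower in set 2. These were macrophage genes (12 of 13 fell, Lyz2 at -2.38 ± 0.23), fibro-adipogenic progenitor genes (8 of 9 fell, Dpt at -1.83 ± 0.12) and adipocyte genes (6 of 12 fell, Adipoq at -3.79 ± 0.34). With an estimated correlation they were not called, at an adjusted p = 0.41, 0.30 and 0.30. The endothelial list was not called (camera adjusted p = 0.095), although 4 of 10 genes rose, among them Cdh5 (1.20 ± 0.16) and Tek (1.10 ± 0.18), and 1 fell. Neither were the Schwann cell list (4 of 10 rose and 3 fell, adjusted p = 0.53) and the lymphocyte list (2 of 5 fell, adjusted p = 0.13).

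In all, edgeR called 5620 of 14225 genes, 2832 higher and 2788 lower in set 2, and 2529 of them changed at least 2-fold. With library size alone as scaling the split was 2102 higher and 3384 lower, and the median of all genes moved by -0.11 on the log2 scale. Camera with a preset correlation called 11 of 26 lists, those above with the slow and fast-fibre lists. With an estimated correlation it called 0, and the smallest adjusted p = 0.12. That setting missed the fast-fibre list, where all 14 genes rose, and the slow-fibre list, where all 13 fell. Its lack of a call in the treatment comparisons therefore cannot decide whether a list changed.

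The second comparison asked what maternal protein restriction changed, averaged over both sets. A single transcript row passed the threshold. Counts in the row of Trnn, the mitochondrial tRNA for asparagine, fell by 2.04 on the log2 scale (SE 0.25, edgeR adjusted p = 0.012). The set 2 value of Trnn was -0.35, and Trnn was not called without control 9, without restriction 12 or without restriction 13. Strand is not marked, so reads of this tRNA and of an antisense partner cannot be told apart in this row. Matrix genes of tendon and cartilage had higher values in restriction libraries, and the small heat-shock protein Hspb7 and the myogenic factor Myog had lower ones, none of them passing over all genes. Fibromodulin (Fmod), which binds collagen fibrils, measured 40.7 ± 9.63 CPM in set 1 controls and 78.1 ± 30.9 in set 1 restriction libraries (SD), and 89.4 ± 24 and 181 ± 36.9 in set 2, for a mean log2 fold change of 0.98 ± 0.20 (SE, edgeR adjusted p = 0.25).

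Of the 8 genes that the series description names, 2 rose (Fmod, and Chad at 1.23 ± 0.28) and 2 fell (Hspb7 at -1.10 ± 0.23, and Myog at -0.60 ± 0.15) when adjusted over the list alone, and 0 did over all genes tested. The study named these genes from these animals, so the list is not independent evidence. Sdha (-0.04 ± 0.11), Cs (-0.11 ± 0.16), Ldha (0.19 ± 0.14) and Igf1 (-0.06 ± 0.22) were within 2 SE of 0. Among genes with a symbol, those with the smallest p among higher values were Fmod, Crabp1, Fhod1 (0.50 ± 0.10), Espl1 (0.98 ± 0.20) and Prelp (0.65 ± 0.14), each at an edgeR adjusted p = 0.25 and not passing. The locus LOC680077, which has no such symbol and was named after its values were seen, had a smaller p (1.26 ± 0.25, edgeR adjusted p = 0.25) and did not pass either. Crabp1 had a mean of 0 CPM in set 2 controls and 0.341 CPM in set 2 restriction libraries.

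**Figure D2:**
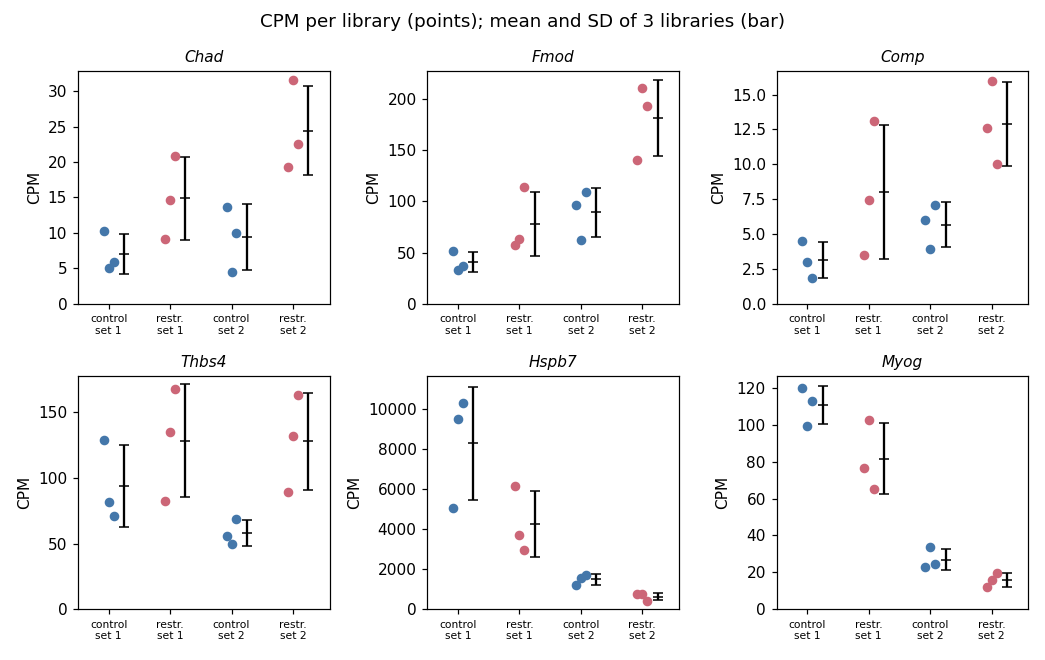
CPM (linear axes) of 6 genes, with 1 point per library and a bar for the mean and SD of 3 libraries, in control (blue) and restriction (red) libraries of each set. Mean Fmod was 40.7 and 78.1 CPM in set 1 and 89.4 and 181 CPM in set 2, and mean Hspb7 was 8280 and 4280 CPM in set 1 and 1490 and 626 CPM in set 2.

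By list, camera with a preset correlation called 8 of 26 for the mean effect, none of which it called in set 1 alone. Tendon and cartilage matrix genes were higher, with 15 of 16 values above 0 and a median of 0.75 (adjusted p = 8.8e-07, and adjusted p = 0.37 with an estimated correlation). Adjusted over the list alone 5 rose, among them Comp (1.27 ± 0.30) and Thbs4 (0.80 ± 0.20), and 0 rose over all genes. Of the 5, 4 were kept in 12 of 12 fits that left out 1 library, and Cilp2 in 7. Immediate early genes, the first transcripts induced by stimulation, were lower, with 14 of 15 values below 0 and a median of -0.85 (adjusted p = 5.6e-07, and adjusted p = 0.37 with an estimated correlation). Adjusted over the list alone 7 fell, including Egr1 (-1.24 ± 0.34), Egr3 (-1.48 ± 0.33) and Btg2 (-0.84 ± 0.16), and 0 over all genes. Of the 7, 5 were kept in 12 of 12 such fits, Junb in 11 and Klf4 in 4. Red blood cell genes were lower in 6 of 6 values, with a median of -1.27 (adjusted p = 5.6e-07, and adjusted p = 0.37 with an estimated correlation), and all 6 fell adjusted over the list alone, among them Alas2 (-1.20 ± 0.29). Globin genes are near-identical copies, so Hba1 (-0.97 ± 0.27) is uncertain, and control 23 held 0.202% globin counts against 0.0649% to 0.0919% in the other controls. Without control 23 the median of the list was -0.77.

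The lists of oxidative metabolism had small negative medians, at -0.16 for fatty acid oxidation, -0.26 for slow-fibre genes, -0.14 for the citric acid cycle and -0.08 for nuclear oxidative phosphorylation genes, while the myelin and Schwann cell list had a median of 0.39. Their adjusted p were 0.0011, 0.0039, 0.015, 0.032 and 0.0095, and each had an adjusted p = 0.89 with an estimated correlation. No single member of these 5 lists passed, even adjusted over the list alone. Leaving out 1 library at a time kept the call in 12 of 12 fits for fatty acid oxidation, 11 for slow-fibre genes, 9 for the Schwann cell list, 7 for the citric acid cycle and 6 for oxidative phosphorylation, whose median was 0.01 without control 23. Without restriction 32 the slow-fibre list had a median of -0.07 (adjusted p = 0.42) and the citric acid cycle list one of -0.08 (adjusted p = 0.16). The Schwann cell list had an adjusted p = 0.087 without control 8 and a median of 0.59 without control 3. In set 1 alone camera gave adjusted p = 0.071 for the matrix, immediate early, red blood cell and fatty acid oxidation lists. It gave 0.061 there for the Schwann cell list and 0.35 for the slow-fibre, citric acid cycle and oxidative phosphorylation lists, the last with a median of 0.10. In set 2 alone it called all of these lists but the Schwann cell list (adjusted p = 0.3). When the libraries were regrouped within sets, 32 of 100 splits called at least as many lists as the labelled groups did.

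**Figure D3:**
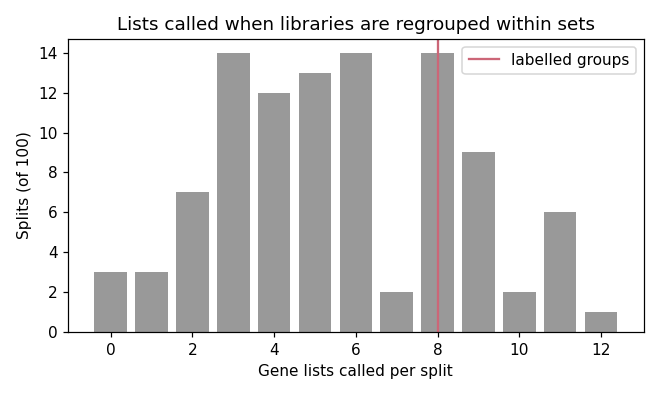
Number of splits (of 100, vertical axis) by the number of gene lists called (horizontal axis) when libraries were regrouped within each set, with a red line at the labelled groups. The labelled groups called 8 lists, and 32 of 100 splits, the labelled one included, called at least as many.

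The circadian clock list was not called (camera adjusted p = 0.76), and its members moved both ways. Adjusted over the list alone Arntl, the core activator also called Bmal1, fell by 1.07 (SE 0.18) and Npas2 by 0.63 (SE 0.23), whereas Dbp (0.89 ± 0.34), Per3 (0.71 ± 0.22), Per2 (0.58 ± 0.20) and Tef (0.40 ± 0.13) rose, and 0 of them passed over all genes. Arntl was kept in 12 of 12 fits that left out 1 library, Tef in 7, Per2 and Per3 in 6, Dbp in 4 and Npas2 in 3, with Dbp at 0.47 without restriction 12.

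At an unadjusted p under 0.05 there were 1114 genes where chance gives 711. DESeq2 called 46 genes and limma-voom 0, and without control 23 edgeR called 8.

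Within set 1, restriction libraries held 0.887 ± 0.184 CPM of Trnn against 11.9 ± 4.06 CPM in controls (SD, n = 3), a fall by 3.74 on the log2 scale (SE 0.37, edgeR adjusted p = 0.00097). The controls measured 8.6, 10.6 and 16.4 CPM. Over the whole library, mitochondrial tRNA took 2.22%, 2.70% and 2.88% of counts in set 1 controls and 4.77%, 4.12% and 4.26% in set 1 restriction libraries, and mitochondrial rRNA 0.246% to 0.302% and 0.328% to 0.384%. The 10 most abundant genes took 22.7% to 23% and 23.8% to 24.2%, and total counts were lower in each restriction library than in each control. These 4 measures separated the diets of set 1 without overlap, which chance gives for 10% of measures. They differed between the same libraries as the gene groups that follow, and a relation to those genes was not tested. Fast-fibre genes had a median of 0.57 and a mean of 0.03 (camera adjusted p = 0.0011, and adjusted p = 0.87 with an estimated correlation). Adjusted over the list alone 5 rose, namely Tnni2 (1.02 ± 0.28), Tnnt3 (1.02 ± 0.31), Tpm1 (1.02 ± 0.31), Tnnc2 (0.71 ± 0.21) and Myh2 (0.84 ± 0.28), and 0 passed over all genes. Tnni2 was lost without restriction 13, and the other 4 without control 9 or restriction 13. Adjusted over the list alone 1 gene fell, Myh4, with a value of -3.47 (SE 1.06). This value rested on control 3, at 396 CPM against 4.97 and 19.5 in the other controls and 9.1, 13.9 and 15 in the restriction libraries. It was 0.06 without control 3. Without control 9 the fast-fibre list had a median of 0.34 and an adjusted p = 0.082, and without control 3 its median was 0.92. Adipocyte genes were below 0 in 12 of 12 values, with a median of -0.73 (camera adjusted p = 0.0025, and adjusted p = 0.70 with an estimated correlation), and none passed over the list alone.

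Besides Trnn, the smallest p among higher values in set 1 belonged to Sh3rf2 (1.09 ± 0.21), Cenpm (2.61 ± 0.56), Tmlhe (0.96 ± 0.21), Hspa4l (2.70 ± 0.59, and 3.29 without control 3) and Nprl3 (0.66 ± 0.15), none passing. Of the 8 genes named by the series description, Chad (1.08 ± 0.40) and Fmod (0.94 ± 0.28) rose and Hspb7 fell by 0.95 (SE 0.32) adjusted over the list alone. Each was lost without control 8, without control 9 or without restriction 15, and they were kept in 6, 9 and 8 of 12 fits. Fmod was at 0.57 without restriction 15, which held 114 CPM against 57.4 and 63.3. Over all genes 0 passed, and Sdha (-0.12 ± 0.15), Cs (-0.36 ± 0.23), Ldha (0.46 ± 0.20), Igf1 (0.21 ± 0.31) and Myog (-0.44 ± 0.21) did not pass in either way. EdgeR called 1 gene, with 1073 at an unadjusted p under 0.05, DESeq2 called 35 and limma-voom 3, and without control 23, a library of the other set, edgeR called 22. Groups did not overlap for 17.6% of genes, where chance gives 10%.

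Within set 2, no gene passed in edgeR. There were 1222 genes at an unadjusted p under 0.05, DESeq2 called 40, limma-voom called 0, and without control 23 edgeR called 4. Immediate early genes were below 0 in 15 of 15 values, with a median of -1.22 (camera adjusted p = 4.4e-07, and adjusted p = 0.35 with an estimated correlation). Adjusted over the list alone 7 fell, including Egr1 (-1.52 ± 0.48), Atf3 (-1.85 ± 0.58) and Junb (-1.42 ± 0.45), and 0 over all genes. Btg2 and Egr3 were kept in 12 of 12 fits that left out 1 library, Egr1, Atf3 and Ier2 in 9, Junb in 8 and Klf4 in 4, with Klf4 at -0.82 without control 29 and -1.23 with all libraries. Tendon and cartilage matrix genes were above 0 in 16 of 16 values, with a median of 1.05 (adjusted p = 9.8e-07, and adjusted p = 0.35 with an estimated correlation), and 5 rose adjusted over the list alone, Cilp2 (1.59 ± 0.40), Chad (1.38 ± 0.40), Comp (1.18 ± 0.42), Thbs4 (1.14 ± 0.29) and Fmod (1.02 ± 0.28). Comp was kept in 6 of 12 fits, and the other 4 in 10, being lost without control 28 or restriction 33. Red blood cell genes had a median of -1.83 (adjusted p = 6.7e-07, and adjusted p = 0.35 with an estimated correlation) and -0.98 without control 23, the library with 0.202% globin counts. Globin took 0.0725% and 0.0919% in the other set 2 controls and 0.0385% to 0.0524% in set 2 restriction libraries.

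Nuclear oxidative phosphorylation genes were below 0 in 31 of 32 values in set 2, with a median of -0.29 (camera adjusted p = 1.3e-05), and without control 23 the median was -0.09 and the adjusted p = 0.14. Slow-fibre genes (median -0.45, adjusted p = 0.0037), fatty acid oxidation genes (median -0.23, adjusted p = 0.017) and citric acid cycle genes (median -0.24, adjusted p = 0.036) were called as lists, without a member passing over the list alone. With an estimated correlation these 4 lists each had an adjusted p = 0.81. Without restriction 32 the slow-fibre list had an adjusted p = 0.96, without control 29 the fatty acid list had a median of -0.10 and an adjusted p = 0.41, and the citric acid cycle list, called in 8 of 12 fits that left out a library, had an adjusted p = 0.34 without restriction 32 and a median of -0.11 without control 23. Among genes with a symbol, those with the smallest p were Tbc1d16, Pml (0.97 ± 0.21), Capns1 (3.69 ± 0.81), Tbc1d4 (1.13 ± 0.26) and Zyg11b (0.97 ± 0.22) among higher values, and Arc (-2.29 ± 0.38), Plk3 (-2.28 ± 0.38), Rd3l (-3.05 ± 0.55), Snai3 (-1.20 ± 0.22) and Btg2 (-1.22 ± 0.23) among lower ones, none passing. LOC680077 (1.75 ± 0.39) had a smaller p than Tbc1d4 and Zyg11b and did not pass. Rd3l was at -1.92 without control 28, which held 4.34 CPM against 1.02 and 0.934 in the other controls. Capns1 measured 24.8 and 28.2 CPM in restriction 32 and 35 but 0.754 CPM in restriction 33, below the controls at 1.18 to 1.52 CPM. It was at 4.25 without restriction 33, and passed in 1 of 12 fits that left out 1 library. Tbc1d16 had 2 counts over set 2 controls, both in control 28, and 82 over set 2 restriction libraries. Of the 8 genes named by the series description, Chad and Fmod rose and Hspb7 (-1.25 ± 0.32) and Myog (-0.76 ± 0.22) fell adjusted over the list alone, and Sdha (0.05 ± 0.15), Cs (0.15 ± 0.23), Ldha (-0.08 ± 0.20) and Igf1 (-0.32 ± 0.32) did not pass. Groups did not overlap for 12.7% of genes, where chance gives 10%.

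**Figure D4:**
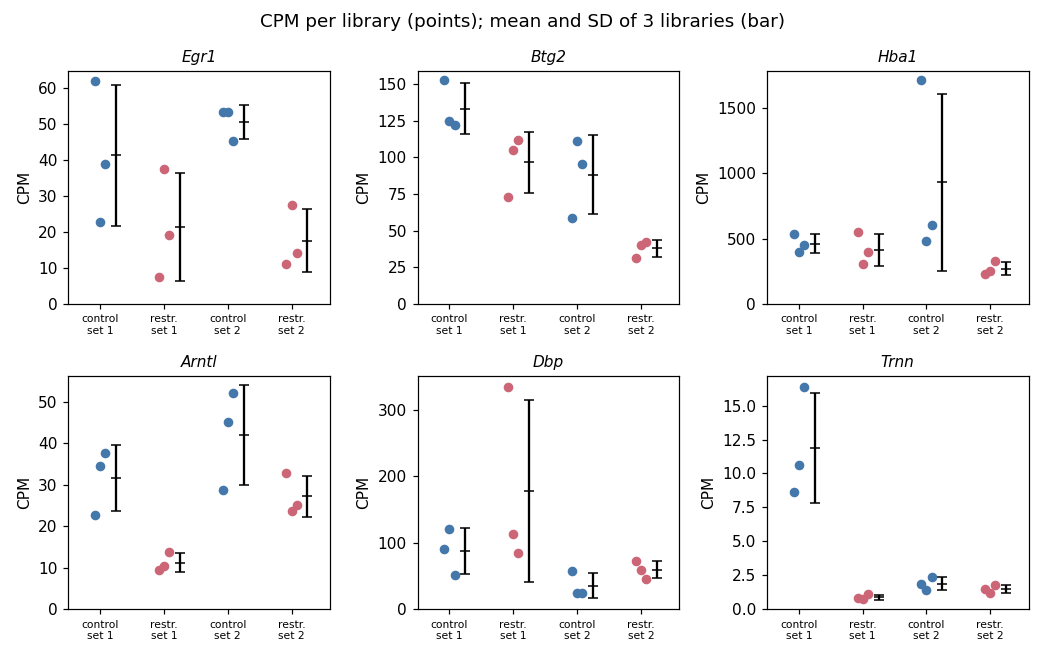
CPM (linear axes) of Egr1, Btg2, Hba1, Arntl, Dbp and Trnn, with 1 point per library and a bar for the mean and SD of 3 libraries, in control (blue) and restriction (red) libraries of each set. Mean Trnn was 11.9 CPM in set 1 controls and 0.887 to 1.88 CPM in the other groups, and mean Arntl was 31.6 and 11.1 CPM in set 1 and 41.9 and 27.2 CPM in set 2.

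The last comparison tested whether the restriction effect differed between the sets. EdgeR called 0 genes, with 1351 at an unadjusted p under 0.05, while DESeq2 called 29 and limma-voom 0. Trnn had the smallest p (3.39 ± 0.49, edgeR adjusted p = 0.098). Gfod1 (1.21 ± 0.20), Lrrfip1 (1.08 ± 0.21), Capns1 (5.61 ± 1.12) and Rab12 (1.80 ± 0.38) had higher effects in set 2, and Rd3l (-3.23 ± 0.67), Rasl2-9 (-6.84 ± 1.45), Sh3rf2 (-1.33 ± 0.29), Palmd (-1.01 ± 0.22) and Cenpm (-3.40 ± 0.76) lower ones, none passing. Rd3l was at -2.09 without control 28, and Rasl2-9 at -5.48 without restriction 15 and -7.79 without restriction 33. Capns1, at 0.754 CPM in restriction 33 against 24.8 and 28.2 in the other set 2 restriction libraries, was at 6.18 without restriction 33. It passed in 1 of 12 fits that left out 1 library. Camera called 4 lists. The effect on fast-fibre genes was lower in set 2 by a median of -0.75 (adjusted p = 0.00054), that on oxidative phosphorylation genes by -0.41 (adjusted p = 0.00054) and that on immediate early genes by -0.72 (adjusted p = 0.035), whereas adipocyte genes had a higher effect, by 1.07 (adjusted p = 0.0021). Leaving out 1 library at a time kept the call of the immediate early list in 5 of 12 fits, with a median of -0.26 without restriction 13. The median of the fast-fibre list was -1.25 without control 3 and -0.49 without control 9, and that of the oxidative phosphorylation list was -0.19 without control 23, with an adjusted p = 0.063 without control 3. With an estimated correlation the adjusted p was 0.97 for the first 3 and 0.75 for adipocyte genes. Across genes the fold changes of the 2 sets had a Pearson r of 0.01, and genes are not independent replicates. Of 141 genes at an unadjusted p under 0.05 in both sets, 67 had the same sign, 33 higher and 34 lower where independent lists give 20.9 and 25. The other 74 had opposite signs, 20 of them higher in set 1 and lower in set 2 and 54 the other way, where independent lists give 19.9 and 26.3. The sets may share animals, so their lists may not be independent.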

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

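The tests of the asparagine tRNA and clock patterns, and the test of mixed muscle, were chosen after the values were seen. Leaving out libraries 1 at a time and the regroupings were fixed earlier. Among 32 groups of 6 libraries tested for a value far from the rest, 5 were found where chance gives about 1.6, and 3 of them belonged to control 23. Control 23 held 5.83% mitochondrial tRNA counts against 2.22% to 3.29% in the other controls, 0.202% globin counts against 0.0649% to 0.0919%, and 27.7% of its counts in its 10 most abundant genes against 22.7% to 23.9%. Restriction 35 held 0.532% mitochondrial rRNA counts against 0.328% to 0.384% in the other restriction libraries, and restriction 32 held 26% of its counts in its 10 most abundant genes against 23.8% to 24.3%. The groups of 6 mix both sets. Within set 1 mitochondrial tRNA separated the diets without overlap, at 2.22% to 2.88% in controls and 4.12% to 4.77% in restriction libraries, as did mitochondrial rRNA (0.246% to 0.302% and 0.328% to 0.384%), while in set 2 the tRNA shares of controls (2.54% to 5.83%) and restriction libraries (1.62% to 3.10%) overlapped.

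The restriction effect differed between the sets by the interaction test with a preset correlation for 4 lists. Medians were 0.57 in set 1 and -0.30 in set 2 for fast-fibre genes (adjusted p = 0.00054), 0.10 and -0.29 for oxidative phosphorylation genes (adjusted p = 0.00054), -0.47 and -1.22 for immediate early genes (adjusted p = 0.035), and -0.73 and 0.50 for adipocyte genes (adjusted p = 0.0021). The regroupings called at least 4 lists in 75 of 100 splits, and up to 12, so chance cannot be excluded for their number. With an estimated correlation the adjusted p was 0.97 for the first 3 lists and 0.75 for adipocyte genes. Leaving out 1 library at a time kept the immediate early call in 5 of 12 fits (median of the difference -0.26 without restriction 13 and -0.72 with all libraries), and the difference for oxidative phosphorylation genes went from -0.41 to -0.19 without control 23 and had an adjusted p = 0.063 without control 3. That for fast-fibre genes, -0.75, was -1.25 without control 3 and -0.49 without control 9.

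Trnn, lower in set 1 restriction libraries, was the 1 gene that edgeR called in set 1 and for the mean, where DESeq2 called 35 and 46, and DESeq2 called 40 in set 2 and 29 for the difference. A different recovery of mitochondrial tRNA as a class is argued against by the other 18 tested rows, whose median log2 fold change in set 1 was 0.10 with quartiles of -0.23 and 1.04, and by the class share, which was higher in set 1 restriction libraries while Trnn was lower. The row with the lowest value among them was Trnc, at -3.22, which lies next to Trnn in the table's order. A mitochondrial sequence variant in set 1 control animals may be a source. It cannot be told apart here from an effect of diet, since it is not established that the sets share animals. Of 6 same-numbered pairs, 5 correlated best with their own number. In shared animals a variant would predict raised Trnn in set 2 controls too. Those held 1.37 to 2.4 CPM, and the log2 fold change in set 2 was -0.35, which would then argue against a variant. An effect of maternal diet on the reads of this row stays open and untested.

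Of 14 fast-fibre genes 10 had values above 0 in set 1 restriction libraries, with a median of 0.57, a mean of 0.03 and Myh4 at -3.47 (0.06 without control 3, at 396 CPM against 19.5 and 4.97 in the other controls and 9.1 to 15 in the restriction libraries), 0 passing over all genes (camera adjusted p = 0.0011, and adjusted p = 0.87 with an estimated correlation). Fast muscle of the set 2 kind mixed into those samples would need a share of 10.4% to give the rise of Myh2, while Myh1 allows at most 1.33% in any of these libraries, Actn3 0.83%, Pvalb 0.58% and Myh4 0.0975%, which argues against it. The test did not cover the controls, so mixed muscle in control 3 was not tested. Control 3 held 161 CPM of Actn3 against 6.02 and 4.97 in the other set 1 controls, and 108 CPM of Pvalb against 3.91 and 5.29. The call rests in part on 1 library, since without control 9 the adjusted p = 0.082. No biological explanation was tested for this pattern.

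The mean log2 fold change of 9 genes (Dbp, Tef, Hlf, Per1, Per2, Per3, Nr1d1, Nr1d2 and Ciart), known as clock genes, 6 above 0 and 3 below 0, minus that of 4 genes (Arntl, Npas2, Clock and Cry1), all 4 below 0, was 0.87 over both sets, 1.21 in set 1 and 0.53 in set 2, where 7 of the 9 were above 0 in each set. Of 100 splits 1, the labelled one, reached 0.87 in absolute size, and the highest other was 0.81, from a split at -0.81. The 100 were the labelled split and others drawn from 200 possible, so a split not drawn may reach 0.87. Within set 1 the largest other of 10 splits was at -1.02, and within set 2 a split at -0.53 matched the labelled one in rounded size and a split at -0.60 exceeded it, and 10 splits are too few for a share under 0.05. That count does not allow for the choice of this list among 26 after its values were seen. A different clock phase at collection may be a cause, and an effect of maternal diet on the muscle clock predicts the same 0.87, and these cannot be told apart because the labels used here give no hour of collection.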

How the results depend on the processing

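The setting without mitochondrial tRNA and rRNA rows was chosen after seeing the data. Set 2 against set 1 kept its count within 1.5 times under every alternative run (4880 to 6450 genes leaving out 1 library). Treatment counts did not. DESeq2 called 35 genes in set 1, 40 in set 2, 46 for the mean and 29 for the difference, and no filter on low counts gave 6, 3, 11 and 1. The cause was not tested. Limma-voom gave 3 in set 1 and 0 for the mean, the set 1 libraries alone gave 5, no set term gave 0 for the mean, and without the mitochondrial rows, which removes Trnn, set 1 and the mean had 0. Leaving out 1 library gave 1 to 22 genes in set 1, 0 to 4 in set 2, 0 to 8 for the mean and 0 to 1 for the difference. The highest values for set 1, set 2 and the mean came without control 23, and that for the difference without restriction 33.

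Called lists numbered 0 with an estimated correlation in each of the 5 comparisons. These included set 2 against set 1, where every slow- and fast-fibre gene was called, so this setting cannot decide on the treatment lists. A filter of mean CPM of at least 1 gave 4 in set 1. Leaving out 1 library gave 1 to 8 lists in set 1, 4 to 8 in set 2, 5 to 11 for the mean, 3 to 6 for the difference and 11 to 13 for set 2 against set 1. The slow-fibre list in set 2 lost its call without restriction 32 (adjusted p = 0.96), where camera's direction turned while the median stayed below 0 (-0.12, with medians from -0.62 to -0.12 leaving out 1 library). The oxidative phosphorylation list for the mean changed direction without control 23 (median 0.01, with medians from -0.14 to 0.01). Over all single lists and alternatives, 447 values kept direction and side of the threshold, 63 lost the call and 2 changed direction. For single genes 1409 values stayed on their side of the threshold, 6 lost the call and 45 gained one. Direction was not compared for genes called in neither fit. Igf1 in set 1, not called, went from 0.21 to -0.10 without restriction 13.

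Same-numbered libraries of the sets had correlated deviations of 0.08 to 0.18, and 5 of 6 correlated best with their own number, as shared animals would predict. The correlation was over 0.1 in only 4 of 6 pairs, so pairing was not taken as established. With the replicate block limma-voom called 3 genes in set 1, 0 in set 2 and 0 for the mean, and edgeR called 0 for the difference and 5421 for set 2 against set 1. At this depth and spread simulated 2-fold changes were recovered at 43% in set 1 and 40% in set 2. Changes of that size can thus be missed. Many genes were changed together in the simulation, and recovery may be lower where few genes change.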

Other observations

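The test of 7 genes (Pdk4, Angptl4, Ucp3, Fbxo32, Cdkn1a, Foxo1 and Fkbp5) and the genes themselves were chosen after the values were seen, from no list fixed earlier and without a test of enrichment. Control 23 had lower values of each than controls 28 and 29. Pdk4, which restrains glucose oxidation, measured 6.06 CPM in control 23 and 642 and 945 CPM in controls 28 and 29. Fbxo32, a muscle ubiquitin ligase, measured 10.4 CPM against 195 and 134, and Fkbp5, a glucocorticoid receptor target, 35.2 against 236 and 280. In set 1, control 3 had the lowest Pdk4 of its group (41.3 CPM against 165 and 381) and the lowest Fkbp5 (17.7 against 89 and 96.8), but its highest Fbxo32 (13.7 against 12.1 and 12.9). Among restriction libraries the lowest Pdk4 values were those of 13 (28.8 CPM) and 33 (55.2 CPM). A shared animal behind libraries 3 and 23, and 13 and 33, may be a cause. Over the 7 genes, same-numbered libraries differed by 0.76 on the log2 scale in their deviations, with an exact one-sided permutation p = 0.056 over 36 arrangements, where the smallest possible is 0.028, so this stays open.

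Regrouping the libraries tested whether chance gives counts as high. For set 2 against set 1, 1 of 100 splits, the labelled one, reached 5620 genes and the highest other gave 2666, so chance can be excluded for the genes. For its 11 lists 21 splits gave as many, with up to 15 in another split. These splits were drawn within each diet, and their sides can hold unequal numbers of set 1 and set 2 libraries. Such splits keep part of the difference between the sets, so this count cannot decide on chance for the number of lists. For the mean restriction effect 12 of 100 splits called at least 1 gene (highest other 2), and 32 called at least 8 lists (highest other 12), so chance cannot be excluded for either. For the difference between the sets all 100 called at least 0 genes, and the highest other gave 30. Within 1 set there are 10 splits, too few for a share under 0.05. The labelled split called 1 gene in set 1 where the highest other called 16 (2 splits reached 1), and 2 lists where the highest other called 14 (9 splits reached 2). In set 2 it called 0 genes where the highest other called 56 (10 splits reached 0), and 7 lists where the highest other called 8 (3 splits reached 7). The split with 16 genes set 3, 13 and 15 apart, and that with 56 genes set 23, 33 and 35 apart. Each was the highest of 10 splits, picked after the values were seen, and a structure of the samples that crosses the diets was not tested. The 2 splits set apart corresponding numbers. The regroupings within sets used 100 of 200 possible splits, drew each set separately and did not keep same-numbered libraries together.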
